A study of Mus musculus with 6 samples.

How the data were processed

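RNA from the frontal cortex of wild-type 129S6/SvEv mice was measured in 6 libraries, 3 from mice given SAHA and 3 from mice given vehicle, which the sample titles call saline. Per the labels' protocols, total RNA was amplified with a whole-transcript kit, labelled with biotin and hybridised to an Affymetrix ST array. Per the submitters' processing notes, Affymetrix Expression Console and RMA were used on the arrays, and no version is named there. The deposited values are on a log2 scale, per the values themselves, with a lowest value of 1.43 and a highest of 14.2 over the 6 arrays. RMA corrects background, normalises between arrays and summarises the probes of a probe set, so a compression or shift of signal on 1 array is spread over its probe sets. The files of scanned intensities were not used here, and neither scan dates nor hybridisation batches are given in the sources used here.

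The table holds 35556 probe sets. In the platform annotation, 21789 of them pair with 1 gene symbol, 1621 with several and 12146 with none. A gene was represented by the probe set of highest mean signal among those pairing with exactly 1 symbol, which gave 19938 genes, 999 of them with more than 1 probe set. The Entrez identifiers of 19855 genes were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. The same table gave the chromosome of each gene, used only to set X-linked, autosomal and mitochondrial genes apart; no positions were used, and 0 columns of per-sample values were left unused. Cdkn1a and H1f0, which the rule for named genes lists, were not analysed here.

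Groups and replicate numbers came from the sample titles. SAHA was compared with saline with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, on the deposited log2 values, with no filter on dim probe sets. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are SAHA minus saline, and standard errors (SE) and 95% confidence intervals are those of the moderated fit. Before the data were examined, 47 gene lists were fixed, covering chromatin enzymes, synaptic and receptor families, stress and metabolic pathways, activity-dependent genes and markers of the cell types that a cortical dissection could hold. Lists with at least 5 measured genes were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 46 lists tested, and again with an estimated correlation and with fry. With an estimated correlation camera also takes the few residual degrees of freedom of the fit. Its p can then rise where genes are not correlated. For blood cell genes the estimated correlation was -0.0028, yet the unadjusted p in camera went from 0.0084 to 0.0513. camera compares a list with the other genes, while fry asks only whether its genes move one way on balance. The list of genes of the mitochondrial genome matched 0 symbols as written, since the annotation holds such genes under short symbols. Under those, 2 of them, COX2 and ND3, are among the genes tested, too few for a list. A list's median was also set against 10000 random lists of the same size, matched on mean signal, and the share of its genes that were lower against the share among all genes in the same bins of signal.

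The genes named were chosen by a rule fixed before the data were examined. It takes 10 genes per direction, by size of the difference among those past the threshold and otherwise by smallest p. They had to lie at or above the median signal, with all 3 SAHA values on one side of all 3 saline values, and predicted genes and chemosensory receptors were left out. To these it adds, from each list past the test, the 3 members of smallest p among those in the direction of the list. Members that moved the other way were therefore not named by it. It also adds a fixed set of histone deacetylases, cortical receptors and Bdnf. Members past the threshold when adjusted over a list alone, and X-linked, Y-linked and mitochondrial genes, are named as well and were chosen after their values were seen.

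The alternatives fixed beforehand were median centring, quantile normalization, a filter at the median signal, the mean of a gene's probe sets, all probe sets, eBayes with a trend or a robust trend, array weights, a plain two-sample test, the replicate number as a block, other thresholds, and each library left out in turn. Cyclic loess normalization and the removal of 2 libraries together were added after the data were seen. In 20 simulations of 3 libraries against 3 with 19938 genes, 200 of them changed, noise was drawn independently for each gene. The fit recovered 15.3% of genes changed by 0.3 log2, 68.7% of those changed by 0.6 and 91.0% of those changed by 1. A mean of 5.2 unchanged genes were called. The simulations held no correlation between genes and no trend with intensity, so these shares do not give the power of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.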

Results

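Chronic treatment with SAHA was compared with vehicle in the mouse frontal cortex. SAHA (suberoylanilide hydroxamic acid, vorinostat) inhibits zinc-dependent histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. Mice received 20 mg per kg SAHA or vehicle for 21 days, and tissue was taken 1 day after the last injection. Each group held 3 libraries, each measured on 1 whole-transcript array, and the number of arrays limits the precision: the median SE of a log2 difference was 0.0771. The labels do not state that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical. The median signal per array lay between 6.66 and 6.71 in saline and between 6.72 and 6.75 in SAHA. The lowest correlation between libraries of 1 group was 0.9945 and the highest between groups 0.9943, across genes, which are not independent replicates.

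2 libraries stood apart in X- and Y-linked transcripts. Xist, the RNA that silences the inactive X chromosome in female cells, had a log2 signal of 10.9 in saline replicate 1 and between 4.63 and 4.88 in the 5 other libraries. The Y-linked genes Eif2s3y, Kdm5d and Uty were at 9.20, 8.11 and 8.19 in the same library, close to their means of 9.22, 8.04 and 8.10 over saline replicates 2 and 3 and SAHA replicates 1 and 2. In SAHA replicate 3 these genes were at 7.80, 7.23 and 6.74, with Xist at 4.76. The results below include both libraries.

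**Figure D1:**
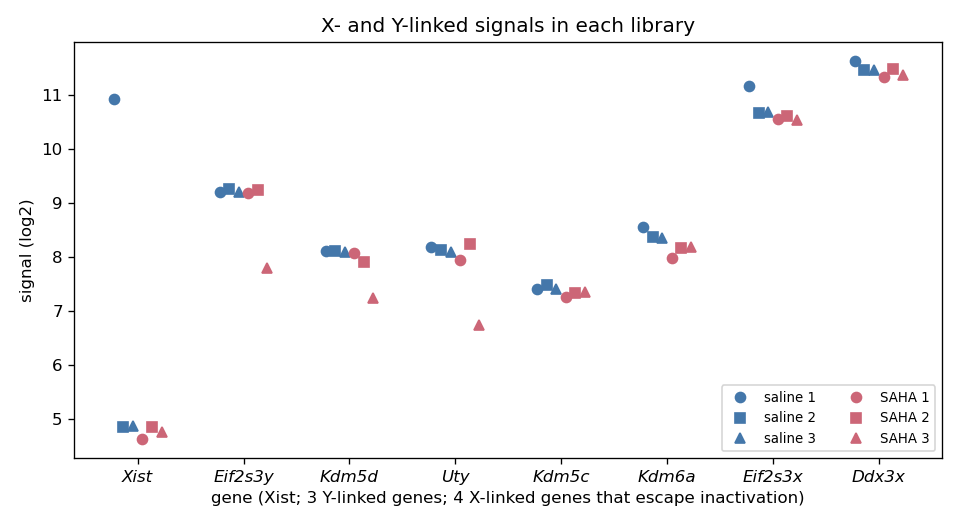
Log2 signal of Xist, 3 Y-linked genes and 4 X-linked genes that escape X inactivation, with 1 point per library (blue saline, red SAHA). Xist stands at 10.9 in saline replicate 1, and the 3 Y-linked genes are lowest in SAHA replicate 3.

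The comparison asks which transcripts of the frontal cortex differ after repeated histone deacetylase inhibition. In limma camera with a preset correlation, 5 of the 46 gene groups tested were lower in SAHA than in saline, relative to the other genes: the nuclear-encoded subunits of oxidative phosphorylation, the subunits of the proteasome, the cytosolic ribosomal proteins, the heat shock proteins and chaperones, and the immediate early genes of neuronal activity. With an estimated correlation 0 lists passed, at a lowest adjusted p of 0.585, and 0 passed with fry. The estimated setting also uses fewer degrees of freedom, so its p-values do not show the effect of the correlation alone. The shifts were small, with list medians between -0.048 and -0.087 log2. After median centring, which moves the difference of every gene by the same amount, they lay between -0.094 and -0.133, and all 5 passed camera. Among the genes named by the rule fixed beforehand, the greatest differences were those of Npas4, an activity-dependent transcription factor of neurons, at -0.58 (SE 0.077), and Zdhhc12, a protein palmitoyltransferase, at 0.57 (SE 0.076). No single gene passed the test: limma with Benjamini-Hochberg adjustment called 0 of 19938 genes, with a lowest adjusted p of 0.116, while 3472 genes (17.4%) were at an unadjusted p under 0.05, where chance gives 997. limma called 27 genes when only genes at or above the median signal were tested, 28 with a variance trend and 31 with a robust trend, and a plain two-sample test called 1. The groups did not overlap for 4773 genes (23.9%), where chance gives 10%.

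Of the 3472 genes, 2364 were higher and 1108 lower in SAHA, and this split moved with the scaling. After median centring 1434 were higher and 2113 lower, after quantile normalization 1606 and 1129, and after cyclic loess normalization 1351 and 1284. The direction of a difference followed the signal. In the dimmest decile of the genes the median difference was 0.069, in the next it was 0.11, and in the brightest decile it was -0.051, with 17.4% of these genes higher in SAHA. The 1194 olfactory and vomeronasal receptor genes, which serve the nasal epithelia, had a median signal of 4.61 and a median difference of 0.10, which was 0.075 after quantile normalization and 0.042 after cyclic loess. The median of the brightest decile was -0.0012 after quantile normalization and 0.0071 after cyclic loess.

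**Figure D2:**
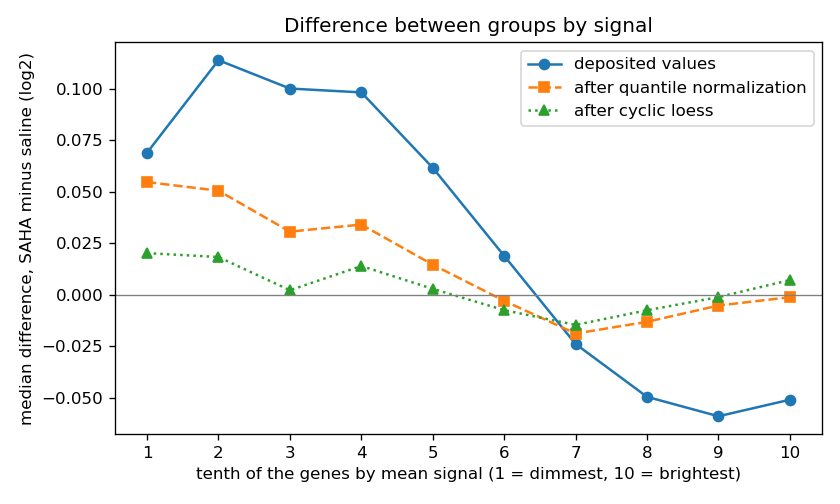
Median log2 difference, SAHA minus saline, in each decile of the genes by mean signal, for the deposited values (circles), after quantile normalization (squares) and after cyclic loess (triangles). In the deposited values it runs from 0.11 in the second decile to -0.059 in the ninth, and after cyclic loess it stays between -0.015 and 0.020.

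The nuclear-encoded subunits of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, had 49 of 63 measured genes lower in SAHA, or 77.8%, where genes of the same signal gave 79.3%. The median difference was -0.064, where random lists matched on signal had a median of -0.050. The test of the list gave an adjusted p of 3.22e-05 (limma camera, Benjamini-Hochberg), and an adjusted p of 0.585 with an estimated correlation. No member passed the limma test over all genes, and 0 passed adjusted over the list alone, while 10 lay at an unadjusted p under 0.05, all of them lower. Among all genes tested, 17.4% lay under it. The members of smallest p were subunits of complex I. Ndufa1 had a log2 signal of 8.61 ± 0.15 in saline and 8.24 ± 0.080 in SAHA (SD, n = 3), Ndufb5 differed by -0.22 (SE 0.063), and Ndufb10 by -0.24 (SE 0.079). Medians over the list were at 0.015, 0.0066 and -0.026 relative to the saline mean in the saline libraries and at -0.10, -0.042 and -0.074 in the SAHA libraries. Of the mitochondrial genome, 2 genes were measured, named after their values were seen: COX2 differed by -0.25 (SE 0.062) and ND3 by -0.17 (SE 0.073), at adjusted p of 0.146 and 0.290 in limma, which were 0.0337 and 0.130 with a variance trend.

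Subunits of the proteasome, which degrades ubiquitin-tagged proteins, were lower for 29 of 31 genes, or 93.5% where genes of the same signal gave 80.7%, with a median of -0.087 and an adjusted p of 0.000141 in camera, or an adjusted p of 0.585 with an estimated correlation. Psmc6, an ATPase of the regulatory particle, was at 9.77 ± 0.064 in saline and 9.54 ± 0.15 in SAHA (SD, n = 3). Psma5 and Psmd13 differed by -0.18 (SE 0.072) and -0.17 (SE 0.062). Of the cytosolic ribosomal proteins, 47 of 53 were lower, or 88.7% where genes of the same signal gave 77.4%, with a median of -0.056 and an adjusted p of 0.000141 in camera, or an adjusted p of 0.585 with an estimated correlation. Rpl7 differed by -0.29 (SE 0.072), Rpl8 by -0.28 (SE 0.084) and Rps2 by -0.16 (SE 0.058). Ribosomal protein genes have many near-identical copies in the genome, and cross-hybridisation of their probe sets was not tested. For both lists, 0 members passed over all genes in limma and 0 adjusted over the list alone. An unadjusted p under 0.05 was reached by 4 proteasome genes and 6 ribosomal protein genes, 5 of the latter lower, and by 17.4% of all genes.

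Heat shock proteins and chaperones, which fold and protect proteins, were lower for 20 of 24 genes, or 83.3% where genes of the same signal gave 72.0%. Their median was -0.079, with an adjusted p of 0.00234 in camera and an adjusted p of 0.65 with an estimated correlation. Cct3, a subunit of the cytosolic chaperonin, was at 8.85 ± 0.063 in saline and 8.51 ± 0.072 in SAHA (SD, n = 3). It was the 1 member past the threshold adjusted over the list alone, and 0 passed over all genes in limma. An unadjusted p under 0.05 was reached by 2 members and by 17.4% of all genes. Tcp1, another chaperonin subunit, differed by -0.14 (SE 0.060), which was -0.089 after quantile normalization, and Chordc1, a partner of Hsp90, by -0.22 (SE 0.11), with overlapping groups for Chordc1. Random lists matched on signal had medians of -0.050 for oxidative phosphorylation, -0.054 for the proteasome, -0.044 for ribosomal proteins and -0.042 for chaperones, and the 4 lists lay at percentiles 6.66, 1.73, 9.75 and 1.97 of these. None of the 4 lists passed camera after quantile normalization, where adjusted p lay between 0.153 and 0.339, after cyclic loess, or among genes at or above the median signal. Nor did any pass with fry, where adjusted p lay between 0.187 and 0.207. The chaperone list also missed the threshold without saline replicate 1 and SAHA replicate 3, at an adjusted p of 0.0996 in camera.

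Immediate early genes, which neurons transcribe within minutes of activity, were lower as a group, with 24 of 41 genes lower, or 58.5% where genes of the same signal gave 52.9%, a median of -0.048 and a mean of -0.092. Random lists matched on signal had a median of -0.0083, and the list lay at percentile 3.12 of these. camera gave an adjusted p of 0.0356, or an adjusted p of 0.65 with an estimated correlation, and fry gave 0.399. Adjusted over the list alone, 5 genes passed, all lower in SAHA, and 0 passed over all genes in limma. An unadjusted p under 0.05 was reached by 11 members, 9 of them lower, and by 17.4% of all genes. Npas4 was at 7.62 ± 0.068 in saline and 7.04 ± 0.12 in SAHA (SD, n = 3), a level 1.49-fold higher in saline. Egr2, a zinc finger transcription factor, was at 9.12 ± 0.15 and 8.66 ± 0.18, and Fos, a subunit of the AP-1 factor, at 7.14 ± 0.033 and 6.88 ± 0.081. The other two were named after their values were seen: Btg2, an antiproliferative gene, differed by -0.59 (SE 0.15) and Ccn1, a matrix-associated signalling protein, by -0.42 (SE 0.11). Medians over the list were at -0.070, 0.021 and 0.082 in saline replicates 1 to 3 and at -0.10, -0.056 and -0.083 in the SAHA replicates, so saline replicate 1 lay within the SAHA range. The call ended without saline replicate 3, at a median of -0.017 and an adjusted p of 0.291 in camera, and without SAHA replicate 3, at an adjusted p of 0.102. It also ended after quantile normalization, at 0.0815, after cyclic loess, at 0.166, and among genes at or above the median signal, at 0.651. It passed without saline replicate 1 and SAHA replicate 3, at a median of -0.065 and an adjusted p of 0.00401 in camera, and after cyclic loess without both, at -0.088 and 0.0113, but with an estimated correlation the adjusted p was 0.818 and 0.949.

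**Figure D3:**
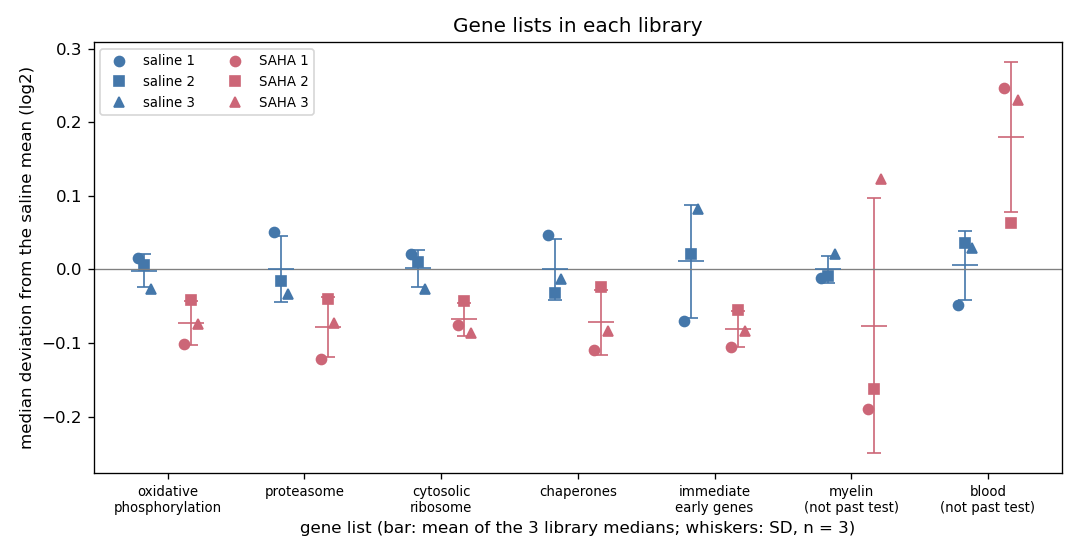
Median deviation of each gene list from the saline mean (log2), with 1 point per library (blue saline, red SAHA), a bar at the mean of the 3 library medians and whiskers of 1 SD. All 3 SAHA libraries lie below all saline libraries for oxidative phosphorylation, the proteasome and the cytosolic ribosome, and the myelin median is 0.12 in SAHA replicate 3 against -0.19 and -0.16 in the other SAHA libraries.

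No list of cell type markers passed the test over all 6 libraries. Percentiles in this paragraph are those among random lists matched on signal. Myelin and oligodendrocyte genes had a median of -0.082, at a percentile of 7.3. Of these, 16 of 21 were lower, or 76.2% where genes of the same signal gave 69.3%. The adjusted p was 0.0784 in camera, or 0.709 with an estimated correlation. The median was -0.034 after quantile normalization and -0.024 after cyclic loess, at adjusted p of 0.499 and 0.582 in camera. Their library medians were -0.19 and -0.16 in SAHA replicates 1 and 2 and 0.12 in SAHA replicate 3, so the list median depended on the SAHA library left out. It was -0.21 without SAHA replicate 3, at an adjusted p of 4.75e-07 in camera, or an adjusted p of 0.376 with an estimated correlation, which was -0.0094. It was -0.010 without SAHA replicate 1 and -0.035 without SAHA replicate 2, at adjusted p of 0.501 and 0.311 in camera. Markers of striatal medium spiny neurons had a median of -0.075, a percentile of 2.73 and an adjusted p of 0.251 in camera, or an adjusted p of 0.739 with an estimated correlation. Without SAHA replicate 3 the median was -0.13, at an adjusted p of 0.0253, or an adjusted p of 0.626 with an estimated correlation, while it was -0.025 without SAHA replicate 2 and -0.034 without saline replicate 3, at adjusted p of 0.565 and 0.726 in camera. Without saline replicate 1 and SAHA replicate 3 it was -0.13 as well, at an adjusted p of 0.0186, or an adjusted p of 0.818 with an estimated correlation. Blood cell genes were higher for 8 of 10, or 80% where genes of the same signal gave 67.8%. Their median was 0.22, at a percentile of 99.5 and an adjusted p of 0.0644 in camera. The alpha- and beta-globin genes of that list were not matched, so it holds none of them. Markers of choroid plexus and ependyma were higher for 10 of 12, or 83.3% where genes of the same signal gave 70.1%. Their median was 0.13, at a percentile of 82.7 and an adjusted p of 0.0784 in camera. With an estimated correlation the choroid plexus list had an adjusted p of 0.585, and its median was 0.066 after quantile normalization, 0.042 after cyclic loess and 0.039 without saline replicate 1 and SAHA replicate 3. The blood list passed camera without SAHA replicate 2, at an adjusted p of 0.0462, and after median centring, at 0.0328, but not after quantile normalization, at 0.175, or cyclic loess, at 0.33. With an estimated correlation its adjusted p was 0.585 over all libraries, 0.576 without SAHA replicate 2 and 0.829 after median centring. Its median was 0.13 without saline replicate 1 and 0.14 without SAHA replicate 1. Excitatory neuron, GABAergic interneuron, astrocyte, microglia, oligodendrocyte precursor and cortical layer markers had adjusted p between 0.222 and 0.824 in camera. Their percentiles were 98.71, 37.04, 99.94, 10.74, 89.35 and 63.9 in that order. Astrocyte and excitatory neuron markers had medians of 0.028 and 0.0016, where random lists matched on signal had -0.042 and -0.044. With an estimated correlation both had an adjusted p of 0.884 in camera.

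On the deposited values, no list of deacetylases, other chromatin enzymes and complexes, histone genes or genes that deacetylase inhibitors raise passed camera. These are RNA levels, which do not measure inhibition of the enzymes. The 18 deacetylases and sirtuins had an adjusted p of 0.372. Hdac1, Hdac2 and Hdac3, the catalytic subunits of nuclear corepressor complexes, differed by -0.023 (SE 0.071), -0.089 (SE 0.071) and -0.088 (SE 0.057), and Hdac6, a cytoplasmic tubulin deacetylase, by -0.10 (SE 0.091). Their adjusted p in limma lay between 0.44 and 0.887, and after quantile normalization Hdac1 was at 0.022, with its sign turned, Hdac2 at -0.030, Hdac3 at -0.025 and Hdac6 at -0.11. Subunits of deacetylase corepressor complexes were lower for 21 of 26 genes, or 80.8% where genes of the same signal gave 67.4%. Their median was -0.032, where random lists matched on signal had -0.041. They had an adjusted p of 0.0784 in camera, or an adjusted p of 0.585 with an estimated correlation. They passed camera after median centring, at 0.0371, or an adjusted p of 0.829 with an estimated correlation, while the median was -0.0052 after quantile normalization and -0.0036 after cyclic loess. Acetyltransferases and acetyl-lysine readers were lower for 12 of 16, or 75% where genes of the same signal gave 70.2%. Their median was -0.051, where matched lists had -0.048, at an adjusted p of 0.0818 in camera. The median was -0.0014 after quantile normalization and 0.0045 after cyclic loess. Histone genes, histone methylation enzymes and the DNA methylation machinery had adjusted p of 0.263, 0.222 and 0.753 in camera. Their medians were -0.037, -0.012 and 0.023, where matched lists had 0.028, -0.040 and -0.029. They lay at percentiles 1.35, 91.59 and 94.5 of these. The histone median was -0.020 after quantile normalization and -0.032 after cyclic loess. Among 15 genes that deacetylase inhibitors raise in cultured cells, 9 were lower, or 60% where genes of the same signal gave 59.2%. The adjusted p was 0.372 in camera. Their median of -0.041, where matched lists had -0.022, was 0.009 after quantile normalization and 0.00011 without SAHA replicate 2. Txnip, an inhibitor of thioredoxin and the 1 member of that list past the threshold adjusted over the list alone, differed by -0.27 (SE 0.059) and was named after its value was seen.

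Grm2, the presynaptic metabotropic glutamate receptor mGlu2, was at 8.50 ± 0.046 in saline and 8.47 ± 0.049 in SAHA (SD, n = 3). The difference of -0.022 had a 95% confidence interval from -0.16 to 0.12 and turned to 0.020 after quantile normalization. Htr2a, the serotonin 5-HT2A receptor of cortical pyramidal neurons, was at 9.67 ± 0.19 and 9.66 ± 0.16, with an interval from -0.28 to 0.25 and a difference of 0.044 after quantile normalization. Bdnf, a neurotrophin that synaptic activity induces, differed by 0.077 (SE 0.064), with an interval from -0.072 to 0.23 and a difference of 0.053 after quantile normalization. All 7 metabotropic glutamate receptors measured were lower, where genes of the same signal gave 66.5%. Their median was -0.049, where random lists matched on signal had -0.040. The list median was 0.011 after quantile normalization and between -0.072 and -0.025 with 1 library left out, and the adjusted p was 0.222 in camera. Ionotropic glutamate receptors, spine actin regulators, postsynaptic density scaffolds and the presynaptic release machinery had adjusted p between 0.222 and 0.494 in camera. They lay at percentiles 32.34, 82.84, 81.59 and 99.52 of random lists matched on signal. The presynaptic median was -0.012, where matched lists had -0.048. GABA, serotonin, dopamine and noradrenaline, and acetylcholine receptors had adjusted p between 0.372 and 0.836.

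Among genes at or above the median signal whose groups did not overlap, 10 were taken in each direction by smallest p. None passed over all genes: their adjusted p in limma was 0.116 for 15 of them and 0.12 for 5. Cbfa2t3, a corepressor that binds histone deacetylases, was at 7.20 ± 0.050 in saline and 7.64 ± 0.058 in SAHA (SD, n = 3), and Oxt, the precursor of oxytocin, at 7.69 ± 0.077 and 8.11 ± 0.037. Tns1, a focal adhesion protein, differed by 0.49 (SE 0.080), Cyp2d40, a cytochrome P450, by 0.55 (SE 0.085), and Tnfsf11, the cytokine RANKL, by 0.42 (SE 0.071). Aurkc, Krtap5-1, Col22a1 and the microRNA gene Mir181c differed by 0.42, 0.45, 0.39 and 0.34. In the other direction, Nop53, a ribosome assembly factor, differed by -0.37 (SE 0.063), the mitochondrial ribosomal protein gene Mrpl42 by -0.35 (SE 0.062), and Srp14, of the signal recognition particle, by -0.31 (SE 0.057). Haus6 and Haus2, subunits of the augmin complex of the mitotic spindle, differed by -0.38 (SE 0.065) and -0.40 (SE 0.078). Ccnyl1, Adamts3 and Zfp958 differed by -0.48, -0.29 and -0.30. Zdhhc12, Cbfa2t3, Oxt, Aurkc, Cyp2d40, Krtap5-1, Tns1, Npas4, Ccnyl1, Nop53, Mrpl42 and Srp14 passed in each of the 3 settings that called 27, 28 and 31 genes, at adjusted p between 0.0328 and 0.0483 in limma. The calls with a trend and a robust trend also held the chemosensory receptor genes Olfr1174, Olfr1329, Olfr197 and Vmn2r9, all higher. Olfr1174 was at 8.27 in saline and 8.73 in SAHA, so a signal above the median does not by itself show expression in this tissue. Of 11 named genes with more than 1 probe set, 10 had the same sign in all of them, but the sizes varied, from 0.093 to 0.42 for the 4 probe sets of Aurkc and from -0.0059 to -0.53 for the 16 of Adamts3.

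**Figure D4:**
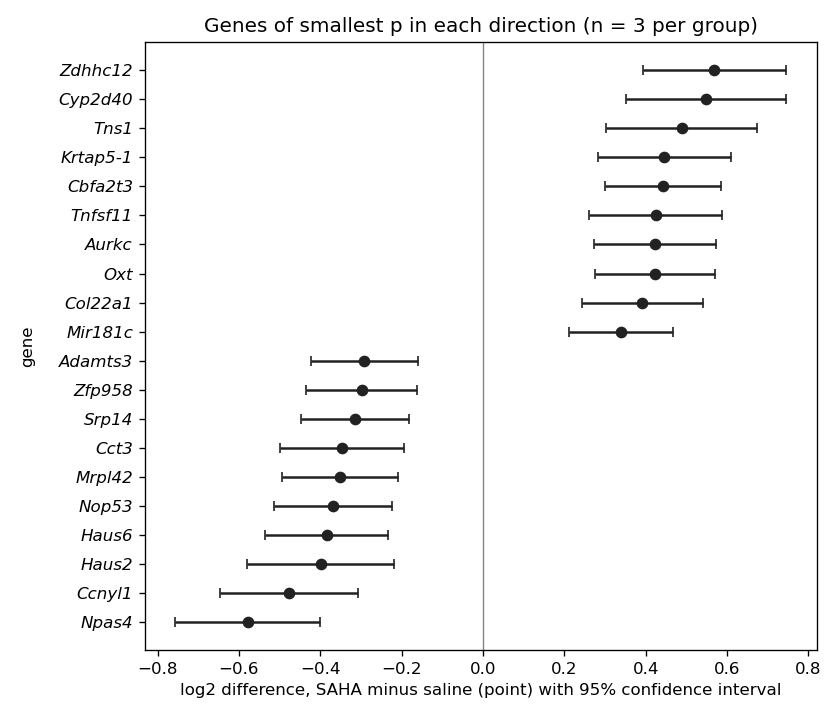
Log2 difference, SAHA minus saline, with its 95% confidence interval from limma, for the 10 genes of smallest p in each direction among those at or above the median signal with non-overlapping groups. They run from -0.58 for Npas4 to 0.57 for Zdhhc12, and none has an adjusted p under 0.05 over all genes.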

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

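Cyclic loess normalization and the removal of saline replicate 1 with SAHA replicate 3 were chosen after the data were seen. The count of genes past the threshold in limma was 0 with all 6 libraries, 0 with each library left out in turn, 27 among genes at or above the median signal, 28 with a variance trend, 31 with a robust trend and 1 with a plain two-sample test. The median-signal filter tests fewer genes and the trend alters the variance prior. 17 genes were shared by the filter, the trend and the robust trend. The count at an unadjusted p under 0.05, 3472, was 1903 above the median signal, 5283 over all probe sets, 1449 with a fold of at least 1.2 as well and 2083 without the 2 libraries; it ranged from 2425 without saline replicate 1 to 3874 without SAHA replicate 2.

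The count of lists past the threshold, 5, was 0 after quantile normalization, above the median signal, after cyclic loess, with an estimated correlation and with fry, and ranged from 4 to 6 with 1 library left out. Quantile normalization left medians of -0.023 for oxidative phosphorylation, -0.039 for the proteasome, -0.016 for ribosomal proteins, -0.041 for chaperones and -0.046 for immediate early genes. Median centring called 7 lists, these 5 among them, at -0.110, -0.133, -0.101, -0.125 and -0.094 in that order. Cyclic loess left -0.014, -0.029, -0.0085, -0.032 and -0.043 in that order. Above the median signal the medians were -0.064, -0.087, -0.056, -0.088 and -0.056, at adjusted p of 0.0758, 0.0758, 0.113, 0.0758 and 0.651 in camera, where the other genes tested are bright as well. With an estimated correlation and with fry the medians are by construction those of the main test, -0.064, -0.087, -0.056, -0.079 and -0.048, and the adjusted p lay between 0.585 and 0.65 and between 0.187 and 0.399. Without the 2 libraries the chaperone median was -0.051. With 1 library left out, the immediate early median ranged from -0.061 to -0.017 and its adjusted p in camera from 4.86e-04 to 0.291. The 4 other lists kept their side of the threshold, with medians from -0.075 to -0.050, -0.11 to -0.064, -0.072 to -0.053 and -0.094 to -0.061. Apart from what these settings do by construction, the cause was not tested.

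The replicate number as a replicate block gave 0 genes past the threshold and 7 lists, adding myelin at an adjusted p of 0.0415 and blood at 0.045 in camera, or adjusted p of 0.701 and 0.674 with an estimated correlation. Libraries of the same number did not deviate together, with correlations across genes of -0.10, -0.079 and 0.015. Of 1106 values of the 62 named genes under alternatives, 1090 kept the sign, and 48 passed an adjusted p of 0.05 in limma. Many of these signs were fixed in advance. The variance trends, the plain test, the signal filter and the replicate block leave the difference itself unchanged. Leaving out libraries cannot turn the sign of a gene whose groups do not overlap. No detection call was used here, so signal over background was not tested for any gene and limits dim genes most.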

Other observations

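The genes named in this paragraph were chosen after their values were seen, as members past the threshold adjusted over their list alone; 0 of them passed over all genes in limma, where their adjusted p lay between 0.116 and 0.205. Blood cell genes included Slc4a1, the anion exchanger of red cells, at 0.38 (SE 0.084), and 3 genes of neutrophils, S100a8 at 0.46 (SE 0.11), S100a9 at 0.21 (SE 0.067), or 0.14 after quantile normalization, and Camp at 0.25 (SE 0.081). Among genes of the meninges and of fibroblasts, the collagen genes Col1a1, Col1a2 and Col3a1 were higher by 0.21, 0.22 and 0.20 and the growth factor Igf2 by 0.20, while the matrix proteoglycan genes Ogn and Omd differed by -0.30 and -0.21. The list as a whole had an adjusted p of 0.935 in camera. Aqp1, the water channel of the choroid plexus, was higher by 0.42 (SE 0.068). In saline, Slc4a1, S100a8, S100a9, Camp, Col3a1 and Aqp1 were at 6.17, 4.76, 5.27, 5.68, 6.43 and 6.24. These lie below the median signal of 6.94, where the median difference of each decile lay between 0.062 and 0.11. Omd, at 5.59, was below it as well but lower in SAHA. Endothelial and pericyte lists both had an adjusted p of 0.263 in camera.

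Among GABA receptors, Gabra5, a subunit of extrasynaptic receptors, differed by -0.29 (SE 0.076) and Gabrq by 0.37 (SE 0.093). Shank2, a scaffold of the postsynaptic density, was higher by 0.36 (SE 0.062), but its 3 probe sets ranged from -0.056 to 0.36. Uhrf1, a partner of the maintenance DNA methyltransferase, was higher by 0.34 (SE 0.070), the receptor kinase gene Ret by 0.30 (SE 0.069) and the dopamine receptor gene Drd4 by 0.24 (SE 0.065). Gabrq, Uhrf1, Ret and Drd4 were at 4.49, 5.95, 6.26 and 6.40 in saline, also below the median signal of 6.94. Inflammatory and interferon genes had an adjusted p of 0.375 in camera, and cell cycle genes 0.753. Glucocorticoid-induced, circadian clock, cholesterol synthesis and unfolded protein response genes had adjusted p of 0.551, 0.322, 0.222 and 0.222. Apoptosis and p53 targets were at 0.936, voltage-gated sodium and calcium channels at 0.26, voltage-gated potassium channels at 0.494, neurotrophins and receptors at 0.647, markers of thalamus and olfactory bulb at 0.883, and sex-linked markers at 0.372.

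Of the tests below, the splits of the libraries for the count of genes, the female RNA tests and the loss of the Y chromosome were chosen after their values had been seen, as were cyclic loess and the removal of libraries.

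Dim genes were higher and bright genes lower in SAHA, which may be an intensity-dependent difference between arrays. Cyclic loess, which removes such a trend, left 0 of the 4 lists of abundant genes past the threshold, with 21.3%, 33.2%, 15.3% and 40.4% of the medians of oxidative phosphorylation, proteasome, ribosomal protein and chaperone genes, so a trend with intensity could account for their calls; a drug effect on abundant transcripts would leave the same trend and was not tested apart from it. After cyclic loess the real split still gave 2635 genes at an unadjusted p under 0.05, where chance gives 997. As far as cyclic loess removes the trend, this argues against it as the whole source of the 3472 before it. The highest of the 9 other splits gave 1215. Each of these 9 mixes SAHA and saline libraries, so any difference between the groups adds to the spread and lowers the count. On the deposited values the real split gave 3472 genes and the highest of the 9 others 1357, and 1 of the 10 splits, the real one, gave as many; for lists the real split gave 5 and the highest other 6, and 2 of the 10 splits gave at least 5. The 10 splits are too few for a share under 0.05.

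The lower immediate early genes are a second pattern, for which a trend with intensity is argued against by the mean over the list, -0.092 (SE over genes 0.032) before and -0.103 (SE 0.031) after cyclic loess. The SE over genes takes the genes as independent, while their estimated correlation was 0.147. At the preset correlation the call of the list ended because of the adjustment over lists. Its unadjusted p in limma camera was 0.00387 before, when it ranked 5 of 46, and 0.00361 after, when it ranked 1. The adjusted p went from 0.0356 to 0.166. With the estimated correlation the unadjusted p in camera was 0.263 before cyclic loess. A treatment effect on activity-dependent transcription and a difference in handling before tissue was taken both remain possible explanations, and neither was tested. Saline replicate 1 had a list median of -0.070, within the range of the SAHA libraries, and without saline replicate 3 the median was -0.017. Npas4, at a lowest saline value of 7.54 and a highest SAHA value of 7.15, kept its groups apart.

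The third pattern is the X- and Y-linked signal of 2 libraries, for which treatment is no explanation that the design could test. In saline replicate 1 the Y-linked genes had a median deviation of 0.0628 (SD 0.032 over 4 other libraries), which shows no loss. Without the Xist level of female RNA on this array, the share that its signal needs is unknown. Xist and the Y-linked genes alone therefore leave female RNA mixed into the library open. An additional X chromosome stays open as well. The median of Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape X inactivation, was 0.269 above the 5 other libraries, and 0.21 after cyclic loess. The same median was 0.091 and 0.042 for 331 other X-linked genes and 0.035 and 0.00027 for 9628 autosomal genes. Of the escape genes, Kdm5c was only 0.041 higher. Female RNA would raise the escape genes too, so they alone cannot tell it from an additional X chromosome. A share of female RNA that raised them this far would also lower the Y-linked genes, which showed no loss. Together these values argue against female RNA as the source of the raised escape genes in this library. A share too small to show in the Y-linked genes stays open for Xist. In SAHA replicate 3, female RNA is argued against by Xist at -0.0432 relative to 4 other libraries, while loss of the Y chromosome from part of the cells remains open, with 3 of 3 Y-linked genes below every other library, at a median of 39.1% of their signal, and escape genes at -0.041. Without both libraries, 2 against 2, the myelin list had a median of -0.22, at an adjusted p of 2.77e-07 in camera, or an adjusted p of 0.818 with an estimated correlation.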
